A study of Mus musculus with 5 samples.

How the data were processed

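The series measured polyadenylated RNA in mouse embryonic stem cells, the cultured pluripotent cells of the early embryo. Per the labels, 3 libraries came from wildtype cells (wildtype 1 to 3) and 2 from cells in which the −45 super-enhancer had been deleted (deleted 1 and 2). A super-enhancer is a dense cluster of enhancers, and this one is named by its distance from the pluripotency gene Nanog. The design text counts 3 replicates per condition, and a further deletion library was not analysed here. Per the labels' protocols, cells were plated in 6-well plates, treated for 6 days with ethanol vehicle or 4-hydroxytamoxifen, and extracted with Trizol and a Qiagen RNeasy kit. Libraries were made with the NEBNext Ultra kit, per the labels. The labels do not say which library received which treatment or whether replicates came from separate cultures or clones, so p-values measure only the spread between these libraries, which may be technical.

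The authors deposited read counts per exon bin, an exon being divided into bins where transcripts differ, as 1 table of 243771 bins and 5 libraries. STAR and the mouse build mm9 are named in the submitters' processing notes, with no version for STAR. The annotation and strand setting of the deposited counts are not given in the sources used here. Of the rows, 78314 bins belonged to 10855 gene symbols and 165401 to 13683 assembly IDs of the form MSTRG plus a number, as transcript assembly produces. The table does not pair those IDs with symbols, so genes under an ID were tested but not named. Symbol rows held 0.328% to 0.375% of each library's counts. Among tested genes, symbol rows had a median log2 CPM (counts scaled to a fixed library size) of −1.12 and ID rows one of 4.39. Reads of a gene with a symbol may be divided with an overlapping ID. Reads from overlapping and antisense genes cannot be told apart without a stated strand. The 56 spike-in names, at 3.20 to 5.08 CPM, were left out of library sizes and tests.

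Totals of bin counts were 125184361, 114838600 and 213042746 in wildtype 1, 2 and 3, and 93574609 and 99134363 in deleted 1 and 2. A read that spans several bins is counted in each, so these totals exceed read numbers. One count was worth 0.00463 to 0.0107 CPM, and 3 counts 0.0139 to 0.0321 CPM. Counts are not independent molecules, so depth covers counting error only. Libraries of each group were compared by chi-square per degree of freedom over tested genes. It was 9.96 between wildtype 1 and 2, 93.4 and 87.4 between these and wildtype 3, and 21.9 between the deleted libraries. Counting a read in several bins raises these values, so they do not by themselves show differences beyond counting noise. No pair was treated as 1 library.

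Here, bin counts were summed per gene. Genes were kept by edgeR's filterByExpr, scaled by TMM and tested with edgeR's quasi-likelihood F test (R 4.3.3, edgeR 4.0.16, limma 3.58.1). Benjamini-Hochberg adjusted p under 0.05 was the threshold, and log2 fold changes are deleted minus wildtype with standard errors (SE). CPM are given as mean ± SD. Before the data were examined, 27 gene lists, the genes around Nanog and a rule for the named genes were fixed. The rule takes every tested gene near Nanog. It takes the 10 largest rises and 10 largest falls past the threshold with a mean log2 CPM of at least 1 and no overlap between groups, leaving out predicted genes and IDs. It also takes up to 4 members per list by p and the 5 genes with the smallest exon-usage p. Lists with at least 5 tested members were compared with all other genes by limma's camera on log2 CPM (prior count 2, correlation 0.01), with Benjamini-Hochberg adjustment over the lists. Exon usage was tested with edgeR's diffSpliceDGE on filtered bins of genes with at least 2 such bins, with Simes p per gene. Symbols were placed on chromosomes with GENCODE vM21 (GRCm38). That build differs from the authors', so no coordinates are given. Values of some single genes of the rule are not reported here. Of the tested symbols, 99.0% had a chromosome and an exon length.

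The tests were tried on simulated data. In gene counts drawn for 16106 genes in the deleted against wildtype layout, 55.2% of genes changed 1.5-fold, 74.6% changed 2-fold and 90.9% changed 4-fold were recovered, and 6.71% of 164 calls were false. Only 200 genes and 1 list were changed there, whereas 39.7% of genes passed the threshold in the real data. The shares recovered and false may therefore not carry over to it. A list raised 2-fold was called, and 0 of 20 unchanged lists were. Simulated genes were drawn independently, so lists of co-regulated or near-identical genes were not covered. In simulated exon usage over 11809 genes, 63% of genes with 1 bin raised 2-fold and 99% with 1 bin raised 4-fold were called. Of 207 calls, 21.7% were false, so this test is liberal here. Lowered bins were not simulated. Alternatives covered the normalization, low-count filters, DESeq2 1.42.0, limma-voom, the most counted bin of each gene, a fold threshold, a stricter adjusted p, a block on the replicate number, other list tests and each library left out. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.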

Results

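RNA of wildtype mouse embryonic stem cells (3 libraries) was compared with RNA of cells lacking the −45 super-enhancer (2 libraries). Bin counts totalled 125184361, 114838600 and 213042746 in wildtype 1, 2 and 3, and 93574609 and 99134363 in deleted 1 and 2. Wildtype 3 was the deepest and stood apart from the other wildtype libraries. Its median log2 difference from them was 0.35 in genes of over 40 bins and −0.07 in genes of 1 to 5 bins, while the deleted minus wildtype medians there were 0.07 and 0.01. The question was how the deletion altered expression, first around Nanog and then across the genome.

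Of the tested genes near Nanog, Foxj2, a forkhead transcription factor gene, was lower in the deleted cells. It averaged 1.39 ± 0.0442 CPM (SD, n = 2) against 2.66 ± 0.217 CPM in wildtype (SD, n = 3), a log2 fold change of −0.94 ± 0.12 (SE; edgeR adjusted p = 0.000499). Apobec1, an RNA-editing cytidine deaminase gene, averaged 2.49 ± 0.105 against 2.23 ± 0.291 CPM. Its log2 fold change of 0.15 ± 0.13 (SE) did not pass (edgeR adjusted p = 0.403). Adjusted over the list alone, the count was also 1 of 3, Foxj2. Of all tested symbols 32.1% passed the threshold, so 1 of 3 is near that share and shows no effect particular to the locus. Nanog and its neighbours Dppa3, Gdf3 and Slc2a3 were not analysed here, since the table does not pair assembly IDs with symbols. The labels were therefore not checked against the targeted gene. In all, 24 symbols within 1 Mb of Nanog or in the fixed list had rows, and 3 had enough counts for a test.

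Across all genes, 3245 were higher and 3208 lower in the deleted cells, together 6453 of 16259 tested (39.7%) at edgeR adjusted p under 0.05. Among genes with symbols, 683 were higher and 469 lower of 3591 tested, 322 and 188 of them by over 2-fold. Together 32.1% of tested symbols passed, the share against which the counts per list below are to be read. At a mean log2 CPM of at least 1, a setting chosen after seeing the data, 82 symbols were higher and 122 lower. Under assembly IDs, 2562 were higher and 2739 lower. For example, MSTRG.16878 averaged 13.9 ± 0.367 CPM in deleted (SD, n = 2) and 1.34 ± 0.0948 CPM in wildtype cells (SD, n = 3), and MSTRG.14257 averaged 0.295 ± 0.0537 against 3.95 ± 0.718 CPM. The total fell to 3555 without deleted 1 and to 4141 without deleted 2, where the lone deleted library was assumed to vary like the wildtype ones. Against a fold change of 1.5, 858 genes passed.

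The largest rise among the 10 named genes was in Zscan4c, a gene of the 2-cell embryo, at 9.37 ± 0.0948 CPM in deleted (SD, n = 2) and 1.62 ± 0.135 CPM in wildtype cells (SD, n = 3). This was a log2 fold change of 2.54 ± 0.10 (SE; edgeR adjusted p = 1.29e-06). Next came Nlrp4c, an oocyte NLR-family gene, with a log2 fold change of 1.76 ± 0.12, and Zfp521, a zinc-finger regulator of neural commitment, with 1.67 ± 0.12. Levels were 3.82 ± 0.176 against 1.13 ± 0.0988 CPM for Nlrp4c and 3.77 ± 0.105 against 1.18 ± 0.134 CPM for Zfp521. The phospholipid flippase gene Atp10a rose by a log2 fold change of 1.43 ± 0.13 and the sarcomere gene Mypn by 1.32 ± 0.13. Slit3, an axon guidance ligand gene, and Kcnj10, a potassium channel gene, followed at 1.16 ± 0.13 and 1.02 ± 0.11. Nell2, Vat1l and the NADPH oxidase gene Nox4 rose by 0.998 ± 0.12, 0.997 ± 0.10 and 0.94 ± 0.14. Vat1l lies on chromosome 8, whose tested symbols had a median log2 fold change of 0.52. Adjusted p-values of these 10 genes were 0.000880 or lower with edgeR.

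Plxdc2, a transmembrane receptor gene, fell most of the 10 named lower genes, from 5.66 ± 0.762 CPM in wildtype (SD, n = 3) to 1.32 ± 0.0472 CPM in deleted cells (SD, n = 2). Its log2 fold change was −2.11 ± 0.14 (SE; edgeR adjusted p = 1.85e-05). Celf2, which encodes a splicing regulator, and Mdga1, a cell adhesion gene, had log2 fold changes of −1.60 ± 0.11 and −1.49 ± 0.14. Elf4, an ETS transcription factor gene on the X chromosome, fell from 5.30 ± 0.542 to 2.05 ± 0.116 CPM, a log2 fold change of −1.37 ± 0.12. Fgfr2, an FGF receptor gene, fell from 2.79 ± 0.1298 to 1.11 ± 0.179 CPM, a log2 fold change of −1.34 ± 0.14. Extl1, the semaphorin gene Sema4c and the interferon-induced gene Oas2 had log2 fold changes of −1.33 ± 0.13, −1.31 ± 0.12 and −1.27 ± 0.13. The homeobox gene Pknox2 and the kinase gene Stk39 had −1.20 ± 0.12 and −1.16 ± 0.12. Adjusted p-values of these 10 genes were 0.000156 or lower with edgeR.

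**Figure D1:**
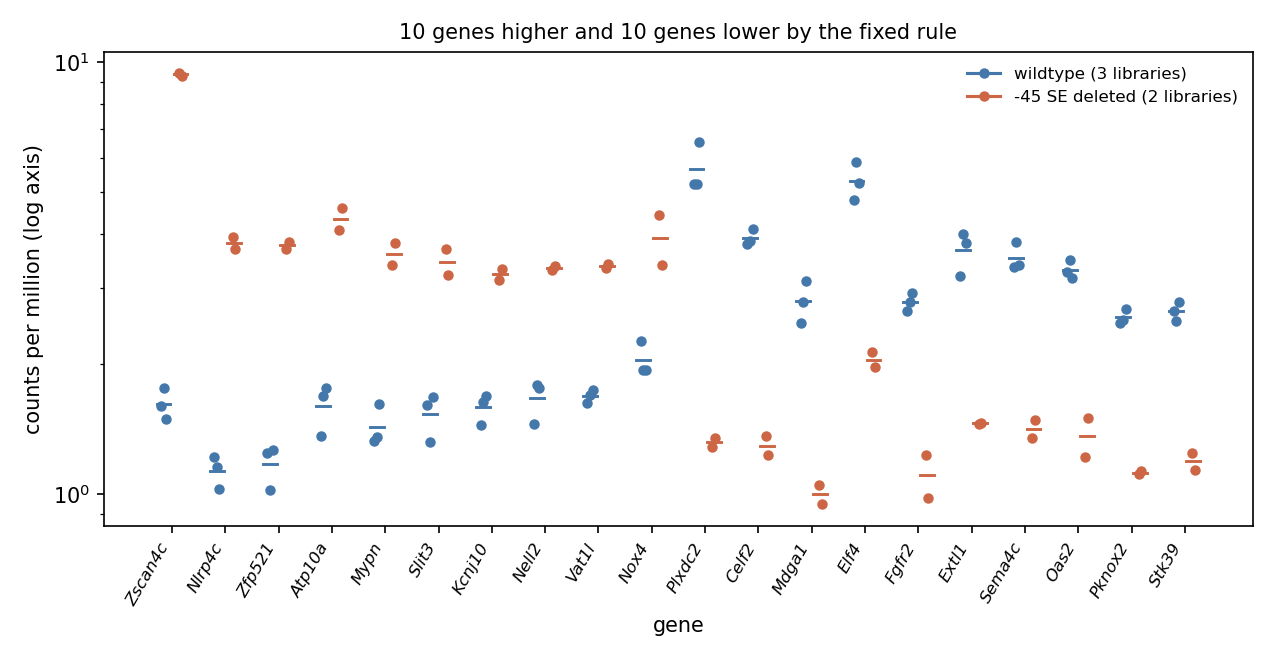
CPM (log axis) of the 10 higher and 10 lower named genes. Each point is 1 library, lines are group means of 3 wildtype and 2 deleted libraries. The groups do not overlap in any of these genes, as the rule for naming them required, and Zscan4c shows the widest gap among the higher genes, at 9.37 against 1.62 CPM.

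All 11 tested members of the two-cell-like list, genes of the 2-cell embryo that a small share of cultured stem cells expresses, were higher in the deleted cells, also 11 when adjusted over the list alone. Their median log2 fold change was 2.40, a 5.30-fold difference. Zscan4b averaged 2.71 ± 0.312 CPM in deleted (SD, n = 2) and 0.534 ± 0.0421 CPM in wildtype cells (SD, n = 3), and Zscan4a 2.08 ± 0.184 and 0.355 ± 0.0762 CPM. Dux, the transcription factor gene that activates the 2-cell programme, stood at 0.149 ± 0.0746 CPM against 0.0218 ± 0.0120 CPM, the latter near the level of 3 counts. The deubiquitinase gene Usp17le rose by a log2 fold change of 2.05 ± 0.26 (SE; edgeR adjusted p = 0.000373) and Tmem92 by 2.41 ± 0.34 (edgeR adjusted p = 0.000740). Zscan4, Usp17l and Dux are families of near-identical copies, so single copies are uncertain. Counts summed over each family gave log2 fold changes of 2.50 ± 0.09 for 3 Zscan4 genes and 2.38 ± 0.20 for 5 Usp17l genes. Of the 26 genes listed, 16 had rows and 11 were tested. The low-count filter could be met by the 2 deleted libraries alone. Members low in wildtype, such as Dux and Tdpoz3, were therefore tested only because they were high in the deleted cells. The count of 11, the median and the list test are thus partly set by the filter. Zscan4a, Zscan4b and Zscan4c had enough counts in wildtype alone. The list was higher than other genes by camera (adjusted p = 2.18e-06). This call was lost with an estimated correlation, at camera adjusted p = 0.122, and no other list was called with either setting. The estimate for this list, −0.049, was below the preset 0.01, so higher correlation among members was not the reason.

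**Figure D2:**
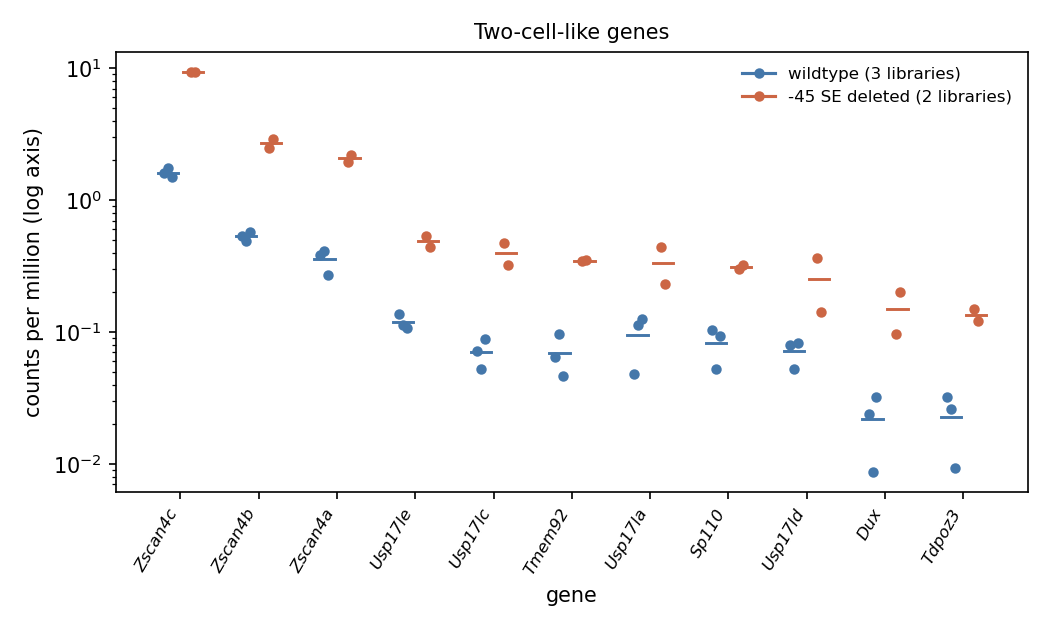
CPM (log axis) of the 11 tested two-cell-like genes. Each point is 1 library, lines are group means of 3 wildtype and 2 deleted libraries. Both deleted libraries lie above all 3 wildtype libraries for each gene, from Zscan4c (9.37 against 1.62 CPM) to Tdpoz3 (0.136 against 0.0226 CPM).

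Of 5 tested formative epiblast genes, 2 were lower and 3 did not pass. Lef1, a transcription factor gene of Wnt signalling, fell from 2.57 ± 0.466 CPM (SD, n = 3) to 1.27 ± 0.0859 CPM (SD, n = 2), a log2 fold change of −1.03 ± 0.17. Fgf5, a marker of the post-implantation epiblast, had −1.64 ± 0.38, with a call that ended without deleted 2 (log2 fold change −1.52). It averaged 0.0678 ± 0.0102 CPM in deleted (SD, n = 2) and 0.216 ± 0.0361 CPM in wildtype cells (SD, n = 3), so its fall rests on few counts. Cdh2, at −0.13 ± 0.15, passed in the most counted bin alone (−0.61; edgeR adjusted p = 0.0391). The list's camera adjusted p was 0.311, while fry, which asks whether the genes move one way on balance, gave 0.0175. Of 13 primitive endoderm genes, 3 were lower, 1 was higher and 9 did not pass. Cubn, an endocytic receptor gene of visceral endoderm, had a log2 fold change of −2.07 ± 0.27 and the transcription factor gene Sox7 one of −0.89 ± 0.16. In the most counted bin alone, Cubn did not pass (log2 fold change −0.80; edgeR adjusted p = 0.169). Pdgfra had −1.02 ± 0.22, not called without deleted 1 (edgeR adjusted p = 0.0665). Gata4 and Gata6, regulators of this lineage, had −0.02 ± 0.16 and −0.24 ± 0.21 (edgeR adjusted p = 0.939 and 0.402). The camera adjusted p of the list was 0.675. Counts adjusted over the list alone matched these in both lists.

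Mesoderm genes moved in both directions, with 2 higher, 3 lower and 8 not past the threshold of 13 tested. Tbx6, a T-box gene of paraxial mesoderm, averaged 0.203 ± 0.00122 CPM in deleted (SD, n = 2) and 0.0536 ± 0.00605 CPM in wildtype cells (SD, n = 3), a log2 fold change of 1.87 ± 0.35. Tbx6 met the low-count filter only in the deleted libraries. Fst, an activin antagonist gene, fell by 0.52 ± 0.09 on the log2 scale. Gsc, an organizer homeobox gene, had a log2 fold change of 1.09 ± 0.30, with edgeR adjusted p = 0.108 without deleted 1 and 0.106 without deleted 2. Nkx1-2 had −0.95 ± 0.25, and its adjusted p was 0.0787 without deleted 1 and 0.0789 without deleted 2. In the trophectoderm list, 3 of 10 were lower and 7 did not pass. These were Fgfr2, Gata2 at −0.80 ± 0.15 and Cdx2 at −1.32 ± 0.44, the last also in the mesoderm and Wnt lists. The Cdx2 call ended without wildtype 1 and without deleted 1 (edgeR adjusted p = 0.0737 and 0.260), and with DESeq2 (adjusted p = 0.0534). Its log2 fold change was −0.75 without deleted 1 and −2.36 without deleted 2. In the neuroectoderm list, Meis1 was higher at 0.72 ± 0.23, Otx1 was lower at −1.01 ± 0.34 and 4 of 6 did not pass. Both calls ended without any single library other than wildtype 3, at edgeR adjusted p of 0.0754 to 0.136 for Meis1 and 0.0657 to 0.240 for Otx1, and with DESeq2 (adjusted p = 0.0726 and 0.0967). In the most counted bin alone Meis1 had 0.14 (edgeR adjusted p = 0.819). Map2, at 0.24 ± 0.13, passed without wildtype 3 (0.34; edgeR adjusted p = 0.0262) and with the replicate block (0.34; 0.0295). The block leaves wildtype 3 without a partner, so these settings for Map2 are nearly the same check. Camera adjusted p-values were 0.935 for mesoderm, 0.602 for trophectoderm and 0.843 for neuroectoderm. Median, mean and test differed in sign for the mesoderm and neuroectoderm lists. Adjusted over the list alone, each count was unchanged.

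Among markers of fibroblasts, the usual feeder cells of such cultures, 4 of 8 were higher, none was lower and 4 did not pass. All 4 were collagen genes. Col1a2 had the smallest p of these (edgeR adjusted p = 0.00489). It averaged 0.797 ± 0.0852 (SD, n = 2) against 0.424 ± 0.0573 CPM (SD, n = 3), a log2 fold change of 0.92 ± 0.19 (SE). Col6a1, Col5a2 and Col6a2 had 2.09 ± 0.52, 0.75 ± 0.21 and 0.93 ± 0.30. Col6a1 averaged only 0.159 ± 0.0888 CPM in deleted (SD, n = 2) and 0.0349 ± 0.0103 CPM in wildtype cells (SD, n = 3). It met the low-count filter only in the deleted libraries, so the count of 4 is partly set by the filter. Col1a1, the most abundant fibroblast collagen, had 0.18 ± 0.16 (edgeR adjusted p = 0.390) and Fbn1 0.15 ± 0.17 (edgeR adjusted p = 0.520). Calls ended for Col1a2 without deleted 1 (edgeR adjusted p = 0.0551) and for Col6a1 without deleted 2 (log2 fold change 1.34; 0.190). For Col5a2 and Col6a2 they ended without any single library other than wildtype 3, at edgeR adjusted p of 0.0580 to 0.105 and 0.0842 to 0.196. The camera adjusted p of the list was 0.311, and adjusted over the list alone the count was also 4.

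**Figure D3:**
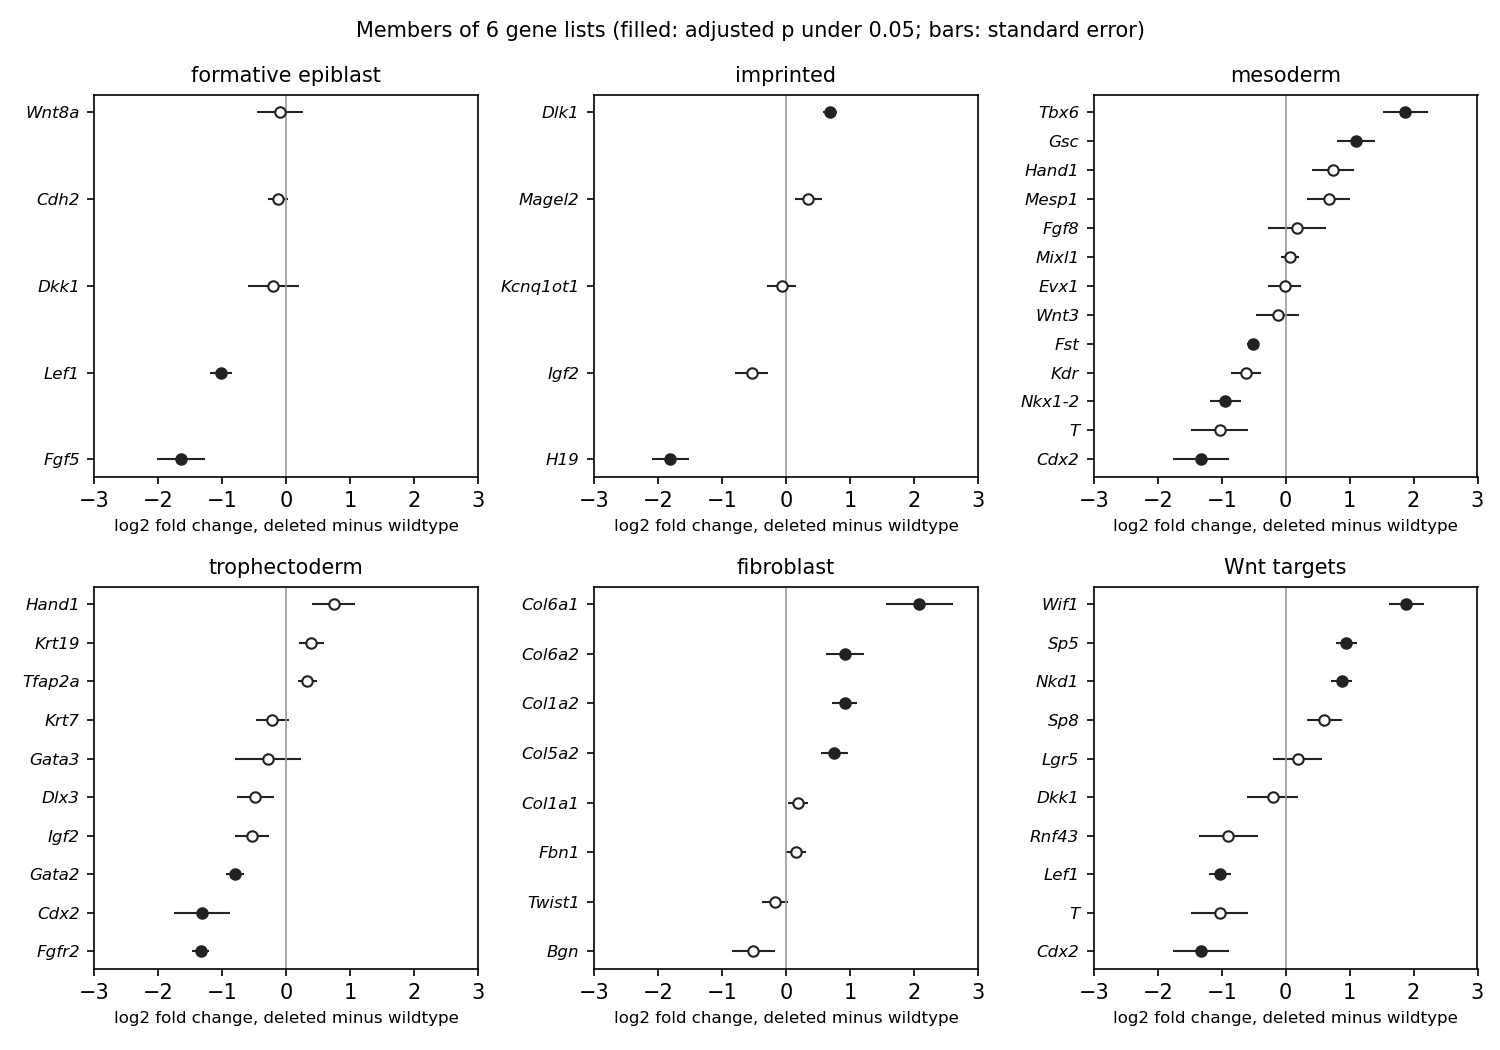
Log2 fold changes (deleted minus wildtype, horizontal axis) of the tested members of 6 lists, 1 gene per line. Bars are standard errors, and filled points passed adjusted p under 0.05. H19 lies lowest in the imprinted list at −1.81. Col6a1 lies highest in the fibroblast list at 2.09, from few wildtype counts. Members of the mesoderm and Wnt lists lie on both sides of 0.

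Of 10 tested Wnt targets, 3 were higher and 2 lower. Wif1, a secreted Wnt inhibitor gene, averaged 0.693 ± 0.177 CPM in deleted (SD, n = 2) and 0.183 ± 0.0522 CPM in wildtype cells (SD, n = 3), a log2 fold change of 1.89 ± 0.28. Sp5 had 0.95 ± 0.17 and Nkd1 0.88 ± 0.16, while Lef1 and Cdx2 were lower. Nkd1 lies on chromosome 8, and in its most counted bin alone it did not pass (log2 fold change 0.45; edgeR adjusted p = 0.214). The camera adjusted p of the list was 0.843, with a median of −0.01 and a mean of 0.002 on the log2 scale and the test pointing up. Of 4 BMP targets, Gata2 and Msx2 were lower and Hey1 was higher. Msx2 had −0.76 ± 0.21, with edgeR adjusted p = 0.0823 without deleted 1 and 0.0898 without deleted 2. Hey1 had 0.41 ± 0.13, and its call ended without wildtype 1, wildtype 3, deleted 1 or deleted 2 (edgeR adjusted p = 0.0675, 0.0533, 0.0935 and 0.174). The Nodal target Gpr161 was higher at 0.63 ± 0.15, a call that ended without deleted 1 (edgeR adjusted p = 0.0938). The only tested LIF and STAT3 target, Bcl6, was lower at −0.66 ± 0.12 (SE; edgeR adjusted p = 0.00273).

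Among 5 imprinted genes, Dlk1 rose from 1.95 ± 0.107 (SD, n = 3) to 3.13 ± 0.0441 CPM (SD, n = 2), a log2 fold change of 0.69 ± 0.10, and H19 fell from 0.950 ± 0.265 to 0.276 ± 0.0190 CPM, a log2 fold change of −1.81 ± 0.29. Igf2, the neighbour of H19, had −0.54 ± 0.26 (edgeR adjusted p = 0.149), and passed without deleted 2 (−0.96; 0.0473) and with the replicate block (−0.51; 0.00987). Among 7 germline genes, 2 were higher, 2 lower and 3 did not pass. Asz1, a piRNA pathway gene, averaged 1.53 ± 0.0428 CPM (SD, n = 2) against 0.188 ± 0.0431 CPM (SD, n = 3), a log2 fold change of 3.04 ± 0.19 (SE; edgeR adjusted p = 1.40e-05). Tex101 had 0.72 ± 0.20, Tdrd1 −0.39 ± 0.11 and Brdt −0.45 ± 0.15. The Tdrd1 call ended without deleted 1 and without deleted 2 (edgeR adjusted p = 0.165 and 0.0553). The Tex101 call ended without any single library other than wildtype 3 (0.0544 to 0.146), and the Brdt call without any other than wildtype 1 (0.0709 to 0.164). Camera adjusted p-values were 0.996 for the imprinted and 0.935 for the germline list. In the germline list the median was negative while the mean and the test pointed up, and in the imprinted list camera pointed down and fry up. The methylcytosine dioxygenase gene Tet3 was lower at −0.70 ± 0.14 (edgeR adjusted p = 0.00420). The Y-linked demethylase gene Kdm5d was lower at −0.81 ± 0.26, a call that ended without any single library other than wildtype 3 (edgeR adjusted p = 0.0639 to 0.194). None of the 3 interferon response genes passed (Usp18, Ifi27 and Ifit3; edgeR adjusted p = 0.145, 0.321 and 0.839). Eno2 for glycolysis, Fas for p53 and apoptosis, and Atf3 and Jun for stress had adjusted p-values of 0.167, 0.957, 0.0974 and 0.723 with edgeR. Atf3 passed without wildtype 3 (log2 fold change 0.55; edgeR adjusted p = 0.0374) and with the replicate block (0.57; 0.0320). As for Map2, these settings for Atf3 are nearly the same check. Adjusted over the list alone, counts of higher and lower members were the same in these lists and in the Wnt, BMP, Nodal and STAT3 lists. The remaining 8 lists, among them naive pluripotency, cell cycle and ribosomal proteins, had no tested symbol.

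Exon usage, the share of a gene's counts in each bin, differed in 360 of 13045 tested genes, 358 of them under assembly IDs. At the level of bins, 128 were used more and 412 less in the deleted cells of 149501 tested. The first 5 genes by p were all under assembly IDs. Bin 1 of MSTRG.8730 held 1.25% ± 0.147 of the gene's counts in deleted (SD, n = 2) and 4.00% ± 0.404 in wildtype cells (SD, n = 3; edgeR Simes adjusted p = 7.58e-18). Bin 17 of MSTRG.11300 held 2.27% ± 0.0968 against 0.756% ± 0.0628 (edgeR Simes adjusted p = 4.62e-14). Among 1588 symbols, Fgd6 and Gab2, a docking protein gene, passed. Bin 21 of Fgd6 held 11.9% ± 3.03 against 24.5% ± 2.26 (edgeR adjusted p = 0.0193). That call ended without wildtype 1, deleted 1 or deleted 2 (edgeR adjusted p = 0.158, 0.168 and 1), and among bins with at least 10 counts in every library (0.0508). Bin 11 of Gab2 rested on 12 counts in each deleted library and 1, 4 and 6 in wildtype 1 to 3 (edgeR adjusted p = 0.000330). The number of genes was 621 without wildtype 3, 103 without deleted 1 and 124 without deleted 2, and 723 with limma on voom values. An assembly ID may join several genes, and 21.7% of calls were false in simulated bins.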

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

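The settings without chromosome 8 symbols, at a mean log2 CPM of at least 1, and with symbols only were chosen after seeing the data. Of 6453 genes past the threshold (3245 higher, 3208 lower; 683 and 469 with symbols), the counts stayed within 1.5 times under RLE or library-size scaling, DESeq2 (6438), limma-voom, no filter and without chromosome 8 symbols (6380). DESeq2 called 6164 of them in the same direction. A fold threshold of 1.5 left 858 (467 higher, 391 lower; 175 and 96 with symbols), and an adjusted p under 0.01 left 3924 (1954 and 1970; 362 and 241), both by construction. Symbol counts were 284 and 240 at 1 CPM in at least 2 samples and 82 and 122 at a mean log2 CPM of at least 1, since most symbols lie below. The most counted bin alone gave 394 symbols higher, and the cause was not tested. Leaving out each library gave 3555 to 8347 genes (1837 to 4197 higher, 1718 to 4150 lower; symbols 355 to 760 higher, 240 to 492 lower), with no sign change among the 6453. The lowest total came without deleted 1. The locus count stayed at 1, Foxj2, in every setting run.

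The two-cell-like list was the only one past the camera threshold, including under each library left out (adjusted p from 1.96e-07 to 2.09e-05). With an estimated correlation 0 lists passed (two-cell-like 0.122, with an estimate of −0.049 against the preset 0.01). The directional fry test called 2, adding the formative list (0.0175). The mixed fry test, which accepts changes in either direction and compares no list with other genes, called 10, with adjusted p of 0.000945 for formative, 0.0120 for primitive endoderm, 0.000601 for mesoderm, 0.0405 for neuroectoderm, 0.000624 for trophectoderm and for germline, 0.00546 for fibroblast, 0.000414 for Wnt and 0.000607 for imprinted genes. At 1 CPM in at least 2 samples no list kept 5 members, so no test was run.

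For exon usage, 360 genes, 540 bins and 2 symbols became 723, 1047 and 26 with limma on voom values, and the cause was not tested. Testing symbols only gave 2 genes and 2 bins by construction. Each library left out gave 103 to 621 genes, 165 to 1016 bins and 1 to 6 symbols, the lowest number of genes without deleted 1 and the highest without wildtype 3. Whether the replicate numbers pair the libraries could not be settled. Correlations of deviations were 0.0536 and −0.0539 for numbers 1 and 2. The deviations of the 2 deleted libraries are exact opposites, so these are not separate checks. With the replicate block, which leaves wildtype 3 without a partner, 8200 genes and 1 list passed, and exon usage was called in 576 genes, 958 bins and 5 symbols. No row name joined several symbols, so leaving out such rows was not run, while genes joined under an assembly ID cannot be seen here.

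For the 80 single genes and bins followed, none changed direction with a call in 1043 values. Without single libraries, 55 of 395 values, in 21 genes or bins, lost a call and 4 gained one. In other settings 19 of 648 lost a call and 7 gained one. These included Brdt with DESeq2 and limma-voom, Kdm5d with limma-voom, and Tex101, Brdt, Meis1, Otx1, Gpr161 and Cdx2 in the most counted bin alone. With the replicate block the calls of Hey1, Brdt, Otx1 and Cdx2 ended (edgeR adjusted p = 0.0656, 0.0957, 0.0575 and 0.0627), while Igf2, Map2 and Atf3 gained one. Tested symbol rows were low, with a median log2 CPM of −1.12, and the cause was not tested.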

Other observations

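Gene families, chromosomes and the genes named in this part were chosen after seeing the data, as were the tests of shared reads, of the share of chromosome 8 symbols above the median elsewhere, of chromosome 8 members in the two-cell-like list and of X chromosome dose. The other tests were fixed before their results were seen.

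Reproductive homeobox (Rhox) and melanoma antigen (Magea) genes of the X chromosome, known from reproductive tissues, were higher in the deleted cells. All 9 tested Rhox and all 5 tested Magea genes passed, with median log2 fold changes of 2.44 and 3.56. Wildtype means of 3 of these Rhox genes and 1 of these Magea genes lay under the level of 3 counts per library, so these medians rest on few counts. Rhox4b had no counts in wildtype and was at least 5.33-fold higher against that level, which brings the Rhox median to 2.41. The low-count filter could be met by the 2 deleted libraries alone. Members low in wildtype were therefore tested only where they were high in the deleted cells. That all tested members passed, their medians and the family tests below are thus partly set by the filter. Counts summed over all 25 Rhox and all 8 Magea symbols with rows, tested or not, gave log2 fold changes of 2.45 ± 0.22 and 2.70 ± 0.15 (SE). Magea5 averaged 0.912 ± 0.347 CPM (SD, n = 2) against 0.0351 ± 0.0279 CPM (SD, n = 3), and Magea8 0.592 ± 0.0485 against 0.0380 ± 0.0218 CPM. Of 91 symbol families tested by camera, Rhox (adjusted p = 4.04e-05), Zscan (0.00983) and Magea (0.0219) passed, and 0 did with an estimated correlation. Other genes are named for their values alone. Nxf3, an X-linked RNA export gene, stood at 2.93 ± 0.146 against 0.427 ± 0.0675 CPM. Dnajc5g, a testis chaperone gene, stood at 1.62 and 1.35 CPM in the deleted libraries and at 0.00804, 0 and 0.00463 CPM in wildtype 1 to 3. The transcriptional co-regulator gene Cited4 fell from 0.952 ± 0.00295 to 0.162 ± 0.0436 CPM.

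Symbols on chromosome 8 were shifted as a set. Of 166 tested, 69 were higher and 2 lower, with a median log2 fold change of 0.52, against 18.0% higher and 13.7% lower and a median of 0.05 elsewhere. The medians were 0.55 and 0.52 in deleted 1 and 2 and −0.06, 0.02 and 0.05 in wildtype 1 to 3. Named examples are Sorbs2 (log2 fold change 1.64; edgeR adjusted p = 4.46e-05) and Lpcat2 (1.79; edgeR adjusted p = 7.59e-05). Of 20 chromosomes, only this one passed camera (adjusted p = 8.04e-07), and none did with an estimated correlation (adjusted p = 0.187). The estimate for chromosome 8, 0.0075, was below the preset 0.01, so higher correlation was not the reason. Without any single library, 45 to 73 were higher and 1 to 5 lower.

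For this chromosome 8 shift, gene length and expression level are argued against. Its median lay above all of 10000 lists from other autosomes matched on both (percentile 100), the highest of which reached 0.28. Of the 166 symbols, 131 (78.9%) lay above the median elsewhere, a shift spread over many symbols rather than a few. The 95% binomial interval, 71.9% to 84.9%, takes genes as independent. Chromosome 8 was picked for its high median, which already puts most of its symbols above, so this share is no separate test. The lower quartile, 0.13, lay between the 0.1 and 0.2 set in advance as bounds and alone decided nothing. An extra copy of chromosome 8 in the deleted cells, a known change in cultured stem cells, may account for it and would give a log2 value of 0.58. Medians of 4 equal parts of the chromosome by gene order were 0.24, 0.69, 0.78 and 0.36. The lowest lay between the 0.2 and 0.3 set in advance as bounds, so this cannot be told apart from a regional change. An effect of the deletion itself was not tested, because the deletion and any such change fall in the same 2 libraries.

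For the rise of the two-cell-like list, 2 technical explanations are argued against. Reads moving among the near-identical copies with symbols would lower some copies, but all of them rose. The lower log2 fold change of the Zscan4 and Usp17l sums, 2.38, follows from that and is no separate test. Depth of wildtype 3 would remove the rise when that library is left out, but the list's median was then 2.15. Reads shared with copies under assembly IDs were not tested and stay open, as does an extra chromosome 8. Of the 11 members, 10 could be placed and 0 of these lie on it, but an effect through other genes was not tested. The Zscan4 and Usp17l members, most of the list, lie on chromosome 7, so the members are not scattered, independent genes. The deletion itself also stays open as untested, since any other difference between the 2 groups of cultures falls in the same libraries.

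For the Rhox and Magea rise, a higher dose of the whole X chromosome is argued against, since 170 X-linked symbols outside the Rhox and all Mage genes had a median log2 fold change of 0.10 (95% bootstrap interval −0.08 to 0.20). With the 4 Mage genes outside Magea added, the median was also 0.10. Reads moving among the copies with symbols are also argued against, with 2.45 as the lower log2 fold change of the summed Rhox and summed Magea counts. Every tested copy rose, so a rise of these sums was largely given, though they also cover untested copies. Reads shared with copies under assembly IDs were not tested and stay open. The germline list, fixed before the data were examined, had 2 higher and 2 lower of 7 (camera adjusted p = 0.935). An effect of the deletion and one of the history of these cultures were not separated, and both stay open.

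Only chromosomes 7, 8, 12 and X were divided into such parts. Those of chromosome 12 had medians of 0.20, 0.03, 0.41 and 0.75 (4, 2, 9 and 14 symbols higher, 2, 7, 2 and 0 lower), and the third of chromosome 7 one of 0.43 (30 higher and 5 lower of 70). Chromosome 12 as a whole did not pass camera (adjusted p = 0.0853, and 0.558 with an estimated correlation). All 4 tested Y-linked symbols had negative log2 fold changes, of which Zfy1 (−1.96; edgeR adjusted p = 0.000292) and Kdm5d (−0.81; edgeR adjusted p = 0.0341) passed. The real split of the 5 libraries called 6453 genes and 1 of 10 splits reached that number, the real one. The highest of the other splits called 0, and 10 splits are too few for a share under 0.05.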
